A study of Mus musculus with 6 samples.

How the data were processed

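RNA was measured by RNA-seq in mouse alveolar macrophages of 3 groups (control, LPS, LPS + VD3) with 2 libraries each. Per the labels' protocols, RNA was purified with the Qiagen RNeasy Micro kit and libraries were made with the KAPA mRNA HyperPrep kit. The deposited count table holds whole-number counts per gene and library that the authors made from their reads, and the submitters' processing notes name TopHat2, edgeR and the mm10 build without versions or order. The program that counted reads, the annotation, its strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of genes that overlap, have antisense partners or have near-identical copies are therefore uncertain. The deposited second table holds log2 values, and on its values it was checked to equal log2(CPM + 1) of the counts within 0.00423 with library totals over the matched genes. It lists 10343 genes, 16 of them with symbols turned into dates. The 10327 genes matched to the count table each had at least 3 counts in every library, and 241 other genes with such counts had no match in it. It leaves out genes with few counts in 1 library, so 326, 54 and 354 of the genes called here in LPS against control, LPS + VD3 against LPS and LPS + VD3 against control have no matched value there. The counts were used for all main results, and the log2 values only in an alternative.

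The group of each library was taken from the labels. The culture conditions of the control cells and whether libraries came from separate mice are not given in the sources used here. The source names of the LPS + VD3 libraries carry the numbers of the LPS libraries, which hints that libraries of equal number may share cells or a day. The labels do not state this, so no block was used in the main results, and the replicate number as a block is an alternative. The title of LPS 1 belongs to another number series than the titles of the other 5 libraries, which is the only hint of a batch in the labels and falls on 1 library. No library was left out of the main results, and no pair of libraries agreed within sampling noise: chi-square per degree of freedom, over genes with at least 10 counts in the pair, was 2.51 for the control, 26.2 for the LPS and 9.9 for the LPS + VD3 libraries.

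Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 10724 of 23413, and libraries were scaled by TMM. A quasi-likelihood model with 3 group means was fitted to all 6 libraries (glmQLFit without the legacy option, 3 residual and 7.01 prior degrees of freedom, common dispersion 0.021), and each of 3 contrasts was tested with glmQLFTest and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2 scale. Their SE is the size of the fold change divided by the square root of the quasi-likelihood F statistic. For groups near 0 counts, the fold change and this SE also depend on the prior count of the fit. A gene whose group had 0 counts is given as at least N-fold against a floor of 3 counts over that group, and with 1 to 3 counts as a ratio with its 95% exact interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. CPM values are TMM-scaled and given as mean ± SD.

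The genes that the text names follow a rule fixed before the data were examined, as were the main tests, the gene lists and all alternatives but those named last here. The rule takes per comparison the 10 raised and 10 lowered genes with the largest fold change (5 each for LPS + VD3 against control) among genes that passed, had a mean log2 CPM of at least 2, no overlap between the libraries of both groups and a symbol that is not a placeholder. It adds up to 4 members per list with the smallest p, and 16 genes named in advance, among them Cyp24a1, Vdr, Tnf and Cxcl10. A few genes that the rule takes are not reported here. Genes named outside the rule are Il33, Ccl9, Psmb9, Irf7 and Ifit3 in LPS + VD3 against LPS, Tgfbr2 in LPS + VD3 against control and the single genes among the other observations; they were chosen after their values were seen. The 28 lists cover VDR targets, cytokines, chemokines, interferon-stimulated genes, feedback regulators, Tlr4 signalling, alveolar macrophage identity, cholesterol synthesis, LXR and lipid export, antigen presentation, glycolysis and hypoxia, oxidative phosphorylation, antioxidant and metal stress genes, alternative activation, phagocytic receptors, inflammasome, cell cycle, immediate early and stress genes, unfolded protein response, ribosomal proteins, and 8 sets of markers of other cells. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on voom values with the preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. Some genes stand in more than 1 list. Over the lists, the signs of median, mean and tests differed for cytokines with VD3 and for several lists that no test called.

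Genes that answered LPS were chosen by the mean of both LPS groups against control. The choice by LPS against control alone shares the LPS libraries with the VD3 comparison, so its value with no VD3 effect was taken from 20 simulations. These drew each gene independently, with the same spread per gene in all groups and no GC trend. GC percent was computed from the transcripts of GENCODE M21 (GRCm38, the same assembly as mm10), which also gave the gene coordinates, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

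The test was tried on simulated counts with known changes. Each simulation changed 63 to 66 genes per fold, fewer than passed in the data, so its adjustment was stricter than in the data. In LPS against control (10535 genes) it recovered 66.2% of 2-fold and 92.3% of 4-fold changes with 6 false calls. In LPS + VD3 against LPS (10538 genes) it recovered 52.3% of 2-fold and 92.4% of 4-fold changes with 2 false calls. In LPS + VD3 against control (10514 genes) it recovered 68.3% and 92.4% with 13 false calls. The GC offsets were tried on simulated counts of LPS + VD3 against LPS with 10521 genes. A slope of 0.05 log2 units per GC percent was put into LPS 1. The offsets moved rho of unchanged genes from -0.459 to -0.013. With and without them, 91.4% of 4-fold changes were recovered with 17 false calls.

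Alternatives were RLE and upper-quartile scaling, no filter beyond 1 count, at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood fit, limma-trend on the deposited CPM with a pseudocount of 1 or 0.5, fits of the compared libraries only, the replicate number as a block, leaving out each library in turn, and other choices of LPS response genes. No scaling beyond library size and offsets per library that follow GC percent (loess, span 0.3) were added after the data were seen.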

Results

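Alveolar macrophages, the resident phagocytes of the airspaces, were collected by lavage from wild-type mice. Cells were treated in vitro for 4 h with 100 ng/mL lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that is sensed through Tlr4 and Cd14. Other cells received LPS together with 50 nM vitamin D3 (VD3), whose active form is the ligand of the nuclear receptor encoded by Vdr. Control cells formed the third group. RNA-seq gave 2 libraries per group and 6 in all. The total counts were 5022314 and 5454955 in control, 5148787 and 5298428 in LPS, and 5198957 and 5465223 in LPS + VD3. Of 23413 genes listed, 7903 had no count in any library and 10724 entered the tests. Nothing in the labels said that the libraries of a group came from separate mice or cultures, so the p-values measure the spread between these libraries, which may be technical.

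The libraries of a group were not equally close to each other. Pearson's r of log2 CPM across genes was 0.991 between the control libraries, 0.981 between the LPS + VD3 libraries and 0.969 between the LPS libraries. Library LPS 2 was closer to LPS + VD3 1 (r = 0.974) than to LPS 1. The difference between LPS 1 and LPS 2 followed the GC content of the transcripts, with Spearman's rho of 0.669 across genes, against 0.237 for the control libraries and 0.189 for the LPS + VD3 libraries. A GC value was had for 99.3% of the genes tested. Genes are not independent replicates, so no p-value is attached to these correlations.

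LPS against control asked what 4 h of LPS changed in the macrophages. The cells raised inflammatory cytokine, chemokine and interferon-stimulated genes and lowered cell cycle genes, genes of cholesterol synthesis and the vitamin D receptor. Il6, a pyrogenic cytokine, went from 4 counts over both control libraries to 1184 ± 21.1 CPM (SD, n = 2), a log2 fold change of 11.70 ± 0.40 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.53e-08). Tnf rose by 6.63 ± 0.22 (adjusted p = 2.77e-08 in the same edgeR test), from 26.1 ± 1.82 to 2591 ± 520 CPM (SD, n = 2). Klf4, a transcription factor of the monocyte lineage, fell by 5.62 ± 0.28 on the log2 scale (edgeR adjusted p = 3.54e-07), from 111 ± 11.9 to 2.24 ± 0.0226 CPM. On the mm10 build, Il6 lies on chromosome 5 at 30013114 to 30019981, Tnf on chromosome 17 at 35199381 to 35202007 and Klf4 on chromosome 4 at 55527143 to 55532466.

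In the list of inflammatory cytokines and mediators, 16 of 16 tested members rose. Among them Il1b rose by 7.92 ± 0.22 on the log2 scale and Tnfsf15, a tumour necrosis factor family cytokine, by 10.90 ± 0.28. Il12b, the shared subunit of interleukins 12 and 23, had 2 counts in control and 1734 in LPS, a ratio of 1070 (95% counting interval 295 to 8810). Nos2, the inducible nitric oxide synthase, had 0 counts in control and was at least 13.9-fold higher in LPS. Of 17 chemokines, 15 rose and 2 fell. Cxcl1 and Cxcl2, which attract neutrophils, rose by 10.19 ± 0.26 and 9.07 ± 0.22, and Cxcl10, which attracts T cells, had 2 counts in control and 7221 in LPS. All 33 tested interferon-stimulated genes rose, with a median log2 fold change of 4.72. Ifit1 rose by 10.84 ± 0.26 and Rsad2 by 10.17 ± 0.26, both antiviral effectors, and Ifnb1, the gene of interferon beta, was at least 12.3-fold higher (30 counts against 0). Ifit3 had 0 counts in control and was at least 502-fold higher, but it shares much of its sequence with Ifit3b, so its count is uncertain. Oasl1, another antiviral gene, had 3 counts in control and 7441 in LPS. Irg1, the itaconate synthase also called Acod1, rose by 10.23 ± 0.24. All 20 tested feedback regulators rose, among them Tnfaip3, a deubiquitinase that restrains NF-kB, by 4.57 ± 0.18, and Socs3, an inhibitor of cytokine receptors, by 5.24 ± 0.26. Of 22 genes of Tlr4 signalling, 12 rose and 2 fell. The coreceptor Cd14 rose by 4.44 ± 0.26 and the NF-kB subunit Nfkb1 by 2.96 ± 0.15, while Tlr4 itself fell by 0.89 ± 0.26 (edgeR adjusted p = 0.023). The Tlr4 call was lost with no filter beyond 1 count (0.0843), in a fit of the compared libraries only (0.0681) and without control 2 (0.131), LPS + VD3 1 (0.0654) or LPS + VD3 2 (0.059). Adjusted over the list alone, the cytokine, chemokine, interferon and feedback counts were the same, and 13 genes of Tlr4 signalling rose and 2 fell.

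The genes lowered most besides Klf4 were of varied function. The log2 fold change was -5.36 ± 0.33 for the ecto-5'-nucleotidase Nt5e, -4.93 ± 0.34 for the fatty acid elongase Elovl6, -4.86 ± 0.61 for Synpo, -4.85 ± 0.47 for the complement C5a receptor C5ar2, -4.68 ± 0.34 for the sialyltransferase St6gal1 and -4.67 ± 0.33 for Plekha6. Ankrd63 went from 187 counts to 3 and the serotonin receptor Htr2c from 147 to 3.

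Antigen presentation genes rose in 11 of 18 cases with none that fell, and adjusted over the list alone 13 rose and 1 fell. Cd40, a costimulatory receptor, had 0 counts in control and 649 in LPS, at least 266-fold higher, and Tap1, the peptide transporter of class I loading, rose by 2.56 ± 0.25. Of 15 antioxidant and metal stress genes 8 rose, led by the cystine transporter Slc7a11 (3.38 ± 0.23), with Hmox1, the heme oxygenase, at 1.71 ± 0.16. Of 12 inflammasome genes 6 rose, such as Nlrp3 (4.20 ± 0.16), and 2 fell, such as Nlrp1b (-2.68 ± 0.28). Of 25 cell cycle genes 22 fell, and 24 adjusted over the list alone. The replicative helicase subunits Mcm7 and Mcm6 fell by 2.02 ± 0.18 and 1.83 ± 0.16 on the log2 scale. Of 22 cholesterol synthesis genes 14 fell, such as Dhcr7 (-2.31 ± 0.23) and Acat2 (-2.09 ± 0.20), and none rose. Of 28 alveolar macrophage identity genes 14 fell and 8 rose. The TGF-beta receptor Tgfbr2 fell by 2.11 ± 0.15, the lectin Siglec5, listed under this older symbol for Siglecf, by 1.26 ± 0.15, and Pparg, the nuclear receptor that shapes these cells, by 0.80 ± 0.16, whereas the scavenger receptor Marco rose by 1.28 ± 0.15. Without control 2 Pparg lost its call (edgeR adjusted p = 0.0685). Among known VDR targets 5 of 14 rose and 3 fell, and adjusted over the list alone 5 rose and 5 fell. Gadd45a, a growth arrest gene, rose by 2.77 ± 0.25. Vdr fell by 4.19 ± 0.22 (edgeR adjusted p = 5.4e-07), from 78.6 ± 1.92 to 4.28 ± 0.619 CPM (SD, n = 2). Cyp24a1, which inactivates vitamin D hormones, had 5 counts in control and 0 in LPS and did not pass (edgeR adjusted p = 0.0643, but 0.0434 without scaling and 0.0351 with GC offsets).

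The other lists moved in both directions or little. LXR and lipid export genes rose in 2 of 15 cases and fell in 5: the cholesterol exporter Abca1 rose by 3.48 ± 0.18, while Abcg1 and the desaturase Scd2 fell by 1.32 ± 0.16 and 3.54 ± 0.16. Of 10 alternative activation genes 1 rose, the transglutaminase Tgm2, and 5 fell, among them Arg1 (-1.04 ± 0.20, a call lost without control 2 at edgeR adjusted p = 0.0522). Of 17 phagocytic receptors 2 rose and 5 fell, with Fcgr1 at -1.72 ± 0.25 and Mertk at -1.04 ± 0.15. Of 20 glycolysis and hypoxia genes 4 rose, such as Pfkp (1.78 ± 0.15), and 5 fell, such as Pdk1 (-1.96 ± 0.21). Of 15 immediate early and stress genes 5 rose and 3 fell, with Ier3 at 3.28 ± 0.24 and Fos at -2.10 ± 0.32. Of 15 unfolded protein response genes 3 rose, led by Ppp1r15a (2.22 ± 0.23), and 1 fell. Of 24 oxidative phosphorylation genes 1 rose, Uqcrfs1, and of 22 ribosomal protein genes none passed the edgeR test. The Uqcrfs1 call was lost with no filter (0.0794), without scaling (0.134), in both fits of the deposited log2 table (0.148 and 0.149) and without control 1 (0.1), control 2 (0.168) or LPS 1 (0.0753).

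Markers of other cells that a lavage could hold were few and moved apart from each other. Most listed markers had too few counts to test. Tested were 2 of 16 epithelium, 5 of 14 neutrophil, 3 of 17 lymphocyte and 3 of 12 stromal and endothelial markers. Sftpc, Mpo, Cd3e and Col3a1 had 0 counts in every library. Changes of single markers, here and in the other comparisons, therefore do not show a shift of such cells. Of 5 tested monocyte markers 2 rose, led by Vcan (6.46 ± 0.25), and 2 fell. Lcn2 was the 1 of 5 neutrophil markers that rose, from 2 counts to 262. Of 4 dendritic cell markers 2 rose and 1, Clec9a, fell (-1.95 ± 0.29). Of 3 lymphocyte markers 1 rose and 1, Cd2, fell (-1.45 ± 0.21). Pdgfrb, 1 of 3 stromal and endothelial markers, was at least 15.2-fold higher (37 counts against 0). Of 2 lung epithelium markers 1, Cdh1, fell by 2.80 ± 0.19, the 1 eosinophil marker tested, Il5ra, did not pass (-0.21 ± 0.59), and no erythroid marker had enough counts to be tested.

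**Figure D1:**
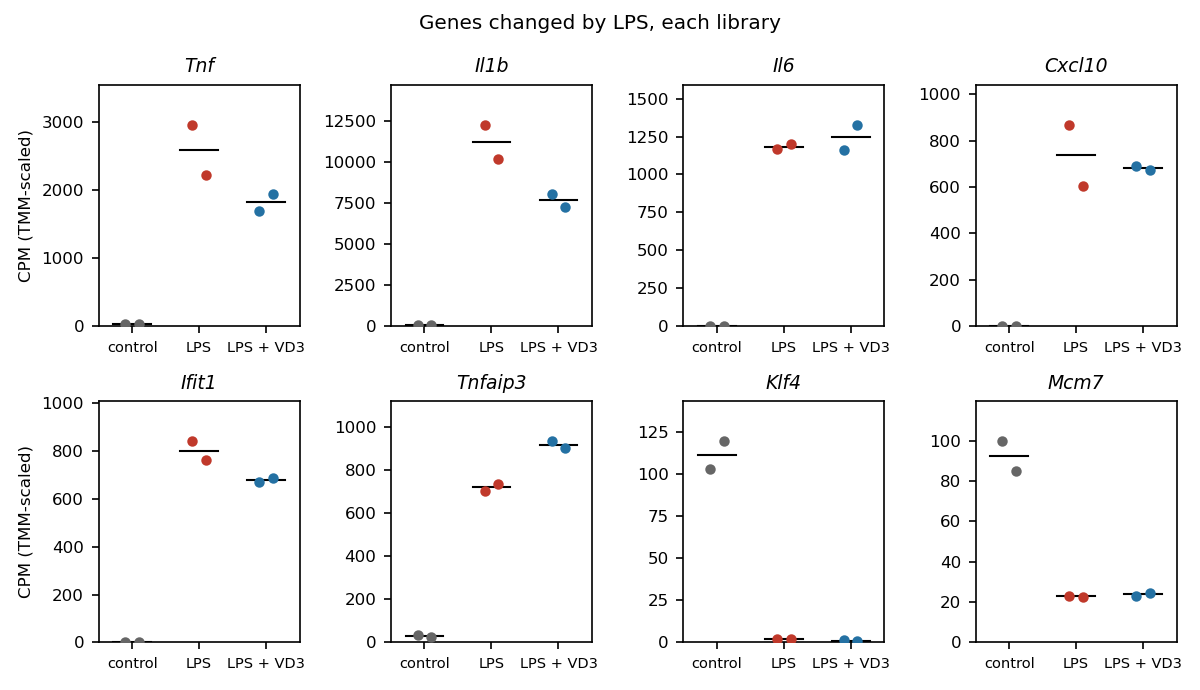
CPM after TMM scaling of 8 genes in each of the 6 libraries (points) with the group mean (line), for control, LPS and LPS + VD3. Il6 and Tnf lie near 0 in control and near 1184 and 2591 CPM in LPS, while Klf4 and Mcm7 are highest in control.

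By edgeR's quasi-likelihood test, 1679 genes were higher and 1732 lower after LPS at adjusted p under 0.05, which is 31.8% of the genes tested, and 985 and 1071 of them changed by at least 2-fold. Without control 1 the count of 3411 genes went to 1975, and without control 2 to 1940. The share of higher calls, 49.2%, was 26.2% without scaling beyond library size, which moves the median of all genes by -0.295, and 24.7% and 24.9% in the deposited log2 table with a pseudocount of 1 or 0.5. With camera at the preset correlation, 10 lists were called: interferon-stimulated, feedback, cytokine, chemokine, Tlr4 signalling, antioxidant, antigen presentation and inflammasome genes upward, cell cycle and cholesterol synthesis genes downward. With an estimated correlation none was called: the adjusted p was 0.0886 for the interferon, cytokine, chemokine, feedback, Tlr4 signalling, antioxidant and cell cycle lists, 0.203 for cholesterol synthesis, 0.227 for inflammasome and 0.427 for antigen presentation genes. The inflammasome call was also lost without LPS 2 (limma camera adjusted p = 0.0506), LPS + VD3 1 (0.0557) or LPS + VD3 2 (0.0519). The alveolar macrophage identity list had adjusted p = 0.0702 (limma camera), and 0.0493 without control 1 and 0.0294 without LPS 1.

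LPS + VD3 against LPS asked what VD3 changed on top of LPS. VD3 raised the VDR target genes Cyp24a1, Hbegf, Vdr and Gadd45a, raised the cytokines Osm, Lif, Csf1, Il12b and Il33 and the chemokines Ccl2 and Ccl7, and lowered Cd40, Socs1, some interferon-stimulated genes and the cholesterol exporters Abca1 and Abcg1. Cyp24a1, the 24-hydroxylase that inactivates vitamin D hormones, had 0 counts in both LPS libraries and 112 and 124 in the LPS + VD3 libraries, at least 78.8-fold higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.32e-05). Hbegf, an epidermal growth factor family ligand, rose from 15.8 ± 0.591 to 197 ± 0.695 CPM (SD, n = 2), a log2 fold change of 3.64 ± 0.19 (SE; edgeR adjusted p = 1.87e-05). Vdr rose by 3.07 ± 0.23 (edgeR adjusted p = 0.000102) to 36.0 ± 4.49 CPM, still below the 78.6 ± 1.92 CPM of control. The genes lie on chromosome 2 at 170482708 to 170497145 (Cyp24a1), chromosome 18 at 36504927 to 36515805 (Hbegf) and chromosome 15 at 97854425 to 97910630 (Vdr), all on the minus strand of mm10.

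**Figure D2:**
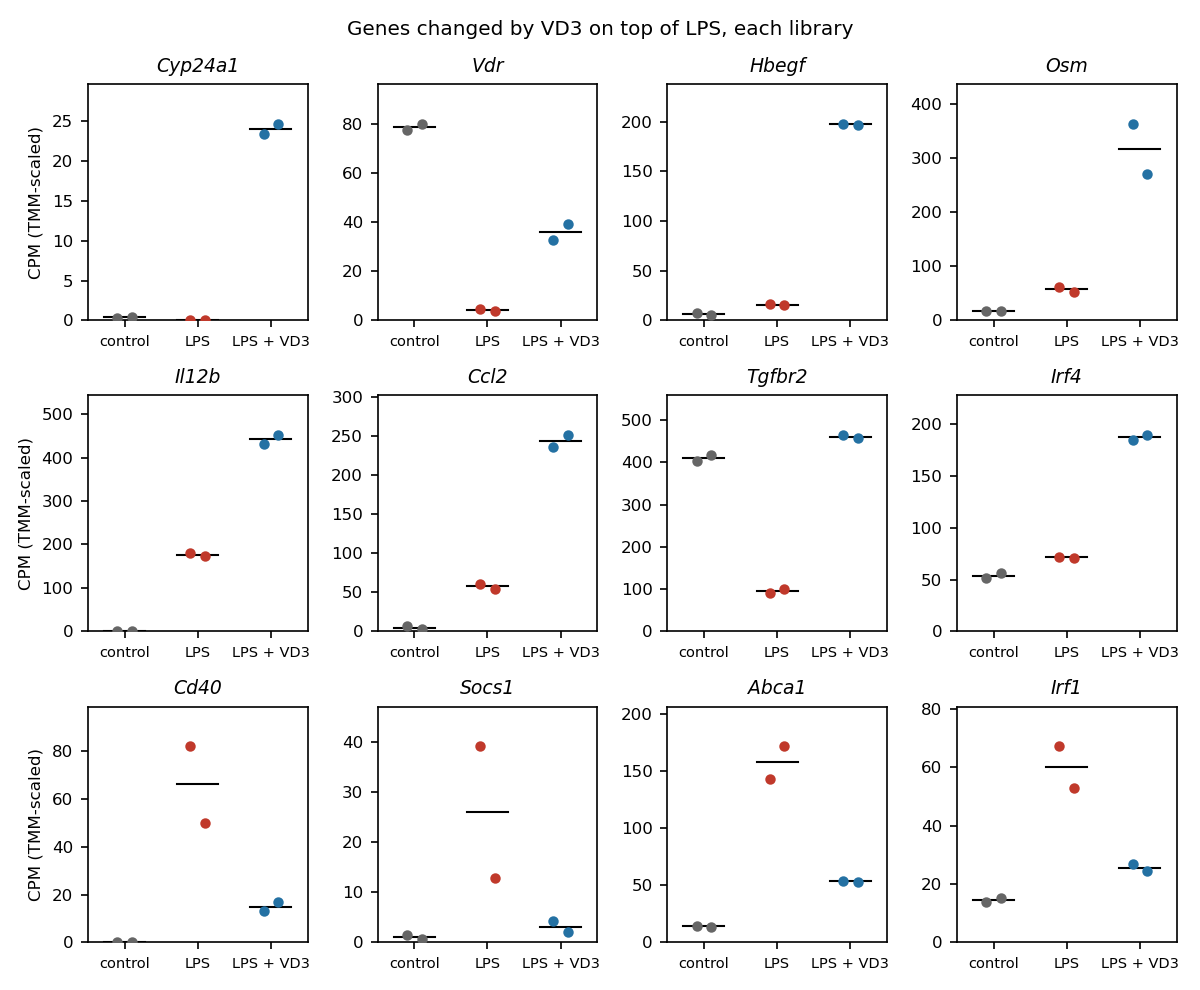
CPM after TMM scaling of 12 genes that passed the edgeR test in LPS + VD3 against LPS, in each of the 6 libraries (points) with the group mean (line). The LPS libraries lie apart for Socs1 (39.2 and 12.8 CPM) and Cd40 (82.3 and 50.2 CPM) and close together for Hbegf (16.2 and 15.4 CPM).

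Further large increases were those of Nppc, the gene of C-type natriuretic peptide, with 1 count in LPS and 256 in LPS + VD3 (ratio 256, 95% counting interval 45.6 to 10200), and of the transcription factors Gata6 (4.69 ± 0.46), Hey1 (4.08 ± 0.37) and Sall2 (3.75 ± 0.29). Gata6 is known from peritoneal macrophages and Hey1 as a Notch target. Srgap3 and Ston2 rose by 3.98 ± 0.29 and 3.78 ± 0.42, as did Art2a-ps by 3.69 ± 0.47, a pseudogene with a close relative that makes its count uncertain. Among genes that fell most, Socs1, an inhibitor of interferon and cytokine receptor signalling, had -3.07 ± 0.57 (edgeR adjusted p = 0.0156) and Cd40 -2.14 ± 0.28 (edgeR adjusted p = 0.00364). The Socs1 call was lost with no filter beyond 1 count (0.111), with limma-voom (0.0533) and without LPS + VD3 1 (0.132) or LPS + VD3 2 (0.302), and the Cd40 call without either LPS + VD3 library (0.104 and 0.0997). Susd2, Lad1, Arap3, Arhgef40 and Rhof had log2 fold changes between -2.69 and -2.32, and Thbs4 had -1.93 ± 0.30. The siderophore-binding protein Lcn2 fell by 1.76 ± 0.33 on the log2 scale.

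In the list of VDR targets 4 of 14 rose and none fell, and adjusted over the list alone 4 rose and 2 fell (limma camera adjusted p = 0.0603). Gadd45a was the fourth at 1.52 ± 0.18. Fry called this list upward (fry adjusted p = 0.0476). The call was reached with camera without LPS 1 (0.00365), LPS + VD3 2 (0.00484), control 1 (0.0354) or control 2 (0.0342) and with GC offsets (0.00931). It was not reached without LPS 2 (0.576) or LPS + VD3 1 (0.163), each with a median of -0.05, with the replicate number as a block (0.0998) or with an estimated correlation (0.628). Of 16 cytokines 5 rose and none fell, and adjusted over the list alone 6 rose and 4 fell. Osm and Lif, of the interleukin-6 family, rose by 2.47 ± 0.19 and 1.62 ± 0.18, Csf1, the macrophage growth factor, by 1.71 ± 0.22, Il12b by 1.32 ± 0.19 and the alarmin Il33 by 2.31 ± 0.39. Il33 lost its call with no filter (0.0594) and without LPS + VD3 1 (0.0536) or LPS + VD3 2 (0.186), Il12b without either of these libraries (0.0613 and 0.0947) and Csf1 without LPS + VD3 2 (0.0733). Il6, Tnf, Il1b and Nos2 did not pass: Il6 was at 0.07 ± 0.21 (edgeR adjusted p = 0.857), Tnf at -0.51 ± 0.17 (0.131), Il1b at -0.55 ± 0.16 (0.10) and Nos2 at -0.28 ± 0.42 (0.727). Il1b passed with DESeq2 (adjusted p = 0.0297), and in edgeR with GC offsets (0.0254) and with the replicate number as a block (0.0253). Both Il1b and Tnf passed without LPS 2, at -0.67 and -0.70. That fit rests on LPS 1 alone, and its fold changes followed GC across genes with Spearman's rho of -0.603. The list's median was -0.06 while limma's camera pointed upward (adjusted p = 0.194). Of 17 chemokines 3 rose and 2 fell, and adjusted over the list alone 3 rose and 5 fell. The monocyte attractants Ccl2 and Ccl7 rose by 2.08 ± 0.20 and 1.98 ± 0.22 and Ccl9 by 0.68 ± 0.15, while Cxcl1 and Cxcl16 fell by 1.01 ± 0.14 and 0.93 ± 0.17 and Cxcl10 was at -0.11 ± 0.17 (edgeR adjusted p = 0.714, and 0.0324 at -0.35 without LPS 2). Of 10 alternative activation genes 3 rose, Irf4 (1.39 ± 0.15), Myc (1.36 ± 0.20) and Tgm2 (1.02 ± 0.16), the same 3 adjusted over the list alone (limma camera adjusted p = 0.0603). That p was 0.00365 without LPS 1, 0.0358 without LPS + VD3 2, 0.041 with GC offsets, 0.0471 with the block, 0.0485 and 0.0483 without control 1 or 2, 0.167 without LPS 2, 0.15 without LPS + VD3 1 and 0.628 with an estimated correlation, and without LPS + VD3 1 or 2 only 2 and 1 of the genes rose.

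Among 33 interferon-stimulated genes 6 fell and none rose, and adjusted over the list alone 12 fell. In fits that leave 1 library in a group, the count was higher without LPS 2 and lower without LPS 1 or either LPS + VD3 library. Without either LPS + VD3 library all 6 lost their calls, while their fold changes kept their sign. With GC offsets, chosen after seeing the data, the count was 12. Irf1, a transcription factor of the interferon response, fell by 1.23 ± 0.19 (edgeR adjusted p = 0.00712), from 60.1 ± 10.3 to 25.6 ± 1.64 CPM (SD, n = 2). The GTPases Igtp and Mx1 fell by 1.22 ± 0.20 and 0.93 ± 0.17, and Ifit2, Ifit3 and Irf7 by 0.90 ± 0.17, 0.86 ± 0.19 and 1.15 ± 0.27 on the log2 scale. The median of the list was -0.48, with 29 of 33 genes below 0 (limma camera adjusted p = 2.88e-07, and adjusted p = 0.628 with an estimated correlation). Without LPS 1 the median was -0.25 with 28 of 33 genes below 0 (limma camera adjusted p = 2.82e-06). Without LPS 2, LPS + VD3 1 or LPS + VD3 2 the medians were -0.70, -0.48 and -0.56. Of 18 antigen presentation genes 4 fell and 1 rose, and adjusted over the list alone 8 fell. Without LPS 2 the count was 14, without LPS + VD3 1 or LPS + VD3 2 none fell, and the median of -0.47 was -0.12 without LPS 1. Tap1, Tap2 and Psmb9, of class I peptide supply, fell by 1.13 ± 0.24, 1.05 ± 0.22 and 1.52 ± 0.34, and Cd80, a T cell costimulator, rose by 1.43 ± 0.19 (limma camera adjusted p = 0.00183, 0.0433 without LPS 1, and adjusted p = 0.628 with an estimated correlation). Of 15 LXR and lipid export genes 4 fell and none rose, 5 adjusted over the list alone. They were Abca1 (-1.56 ± 0.16, edgeR adjusted p = 0.000832), Abcg1 (-1.34 ± 0.17), the receptor Nr1h3 (-1.70 ± 0.27) and the ubiquitin ligase Mylip (-1.66 ± 0.28). For the list, limma's camera gave adjusted p = 0.00224, 0.0144 with GC offsets and 0.628 with an estimated correlation. The list's median of -0.36 was -0.12 without LPS 1 and -0.13 with GC offsets. The 4 became 8 without LPS 2 and 1 without either LPS + VD3 library. Of 20 feedback regulators 3 fell, Socs1, Cish (-1.18 ± 0.22) and Nfkbie (-1.08 ± 0.23), and 5 adjusted over the list alone (limma camera adjusted p = 0.0205, 0.0433 without LPS 1, and adjusted p = 0.628 with an estimated correlation). That call was lost without LPS + VD3 1 (limma camera adjusted p = 0.136) and with GC offsets (0.0607), and the 3 genes became 10 without LPS 2 and none without either LPS + VD3 library.

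Of 28 alveolar macrophage identity genes 1 rose and 2 fell. Tgfbr2 rose by 2.28 ± 0.15 (edgeR adjusted p = 3.95e-05) from 94.9 ± 6.25 to 461 ± 6.06 CPM (SD, n = 2), beside 410 ± 10.7 CPM in control, while Kcnn3, a potassium channel, fell by 1.35 ± 0.16 and F7, coagulation factor VII, by 0.68 ± 0.16. Siglec5, Marco and Pparg did not pass, at 0.17 ± 0.15, 0.05 ± 0.14 and 0.40 ± 0.16 (edgeR adjusted p = 0.522, 0.855 and 0.179), and of these Pparg passed without LPS 2 (0.0454). No cell cycle gene passed, the nearest being Top2a at 0.66 ± 0.16 (edgeR adjusted p = 0.0512), which passed with DESeq2 (0.0251), with the replicate number as a block (0.0125) and without LPS 2 (0.00121), when 6 genes of the list rose. The list lay upward with a median of 0.26 (limma camera adjusted p = 0.0176, and adjusted p = 0.628 with an estimated correlation). The call was lost without LPS 2 or LPS + VD3 1, where the median was 0.04 and 0.21. The median was 0.35 without LPS 1 and 0.14 with GC offsets. No oxidative phosphorylation gene passed either. That list lay downward with a median of -0.22 (limma camera adjusted p = 0.0176, and adjusted p = 0.628 with an estimated correlation). Its call was lost without LPS 1 or LPS + VD3 2, where the median was -0.05 and -0.09. Without LPS 2 the median was -0.39. In the remaining lists single genes passed: Hif1a, the hypoxia transcription factor, at 1.82 ± 0.23 among 20 glycolysis and hypoxia genes, the chaperone Hsph1 (2.08 ± 0.17) and Ier5 (-1.25 ± 0.27) among 15 immediate early and stress genes, the adaptor Ticam2 (1.06 ± 0.17) among 22 of Tlr4 signalling, Naip2 (0.78 ± 0.14) among 12 inflammasome genes, Dnajb9 (1.06 ± 0.21) among 15 of the unfolded protein response and Srxn1 (-0.66 ± 0.15) among 15 antioxidant genes. Srxn1 was at -0.25 (edgeR adjusted p = 0.388) with GC offsets, and its call was also lost with no filter, in a fit of the compared libraries only and without either control or LPS + VD3 library. Ccl9 and Batf3 lost their calls with GC offsets as well (0.162 and 0.0632). None passed among 17 phagocytic receptors, 22 cholesterol synthesis genes and 22 ribosomal protein genes. Of the markers of other cells, Lcn2, Batf3 (-1.39 ± 0.32) and Pdgfrb (-3.13 ± 0.58) fell among 5 neutrophil, 4 dendritic cell and 3 stromal markers. None passed among the lymphocyte, epithelium and eosinophil markers. Cd14, Tlr4 and Ifnb1 did not pass, at -0.36 ± 0.22, 0.11 ± 0.26 and -1.56 ± 0.54 (edgeR adjusted p = 0.337, 0.825 and 0.147). Without LPS 2, in a fit that rests on LPS 1 alone, all 3 passed, at -0.63, 0.65 and -1.83. Cyp27b1, the vitamin D 1-alpha-hydroxylase, and Il10 had at most 2 counts in any library and were not tested.

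**Figure D3:**
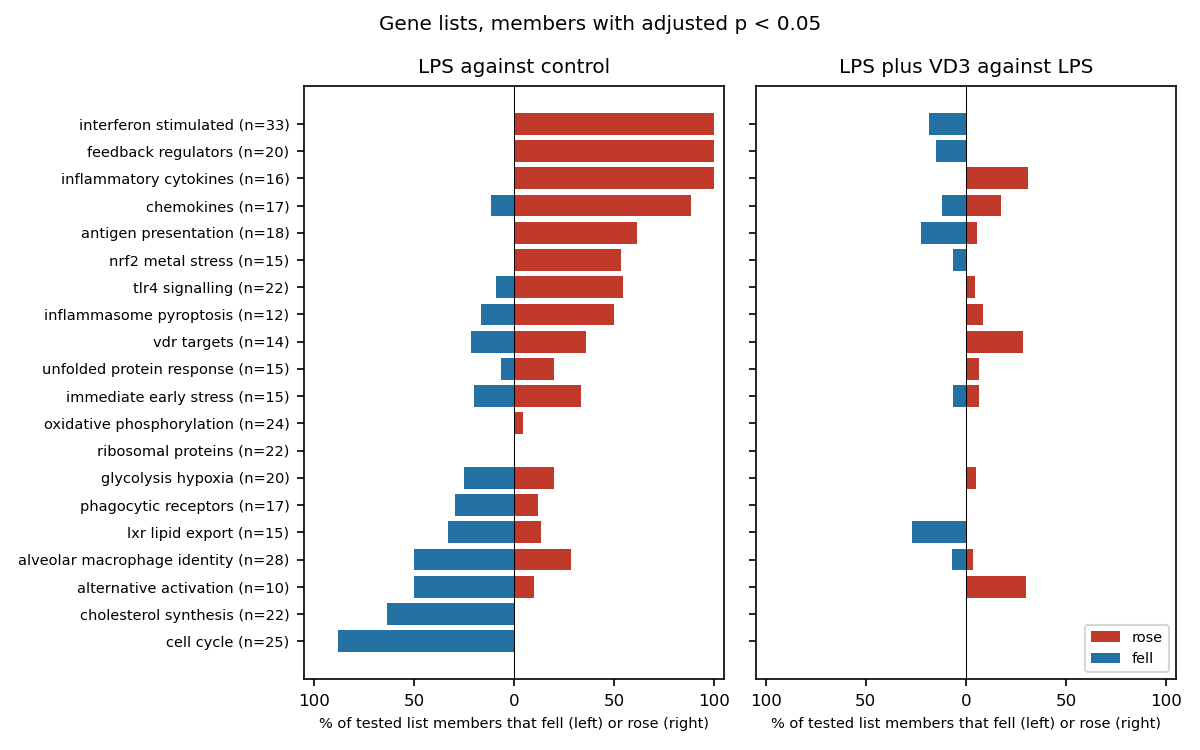
Percent of the tested members of each gene list that rose (right, red) or fell (left, blue) at edgeR adjusted p under 0.05, after LPS against control and with VD3 against LPS; n is the number of members tested. All 33 interferon-stimulated genes rose after LPS, and 6 of them fell with VD3.

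By edgeR's quasi-likelihood test, 241 genes were higher and 170 lower with VD3 at adjusted p under 0.05, 3.8% of the genes tested, and 171 and 95 of them changed by at least 2-fold. On simulated counts for this comparison, with 10538 genes, the test recovered 52.3% of 2-fold and 6.3% of 1.5-fold changes. Smaller changes were mostly missed there, where fewer genes were changed than passed here, which makes the adjustment stricter. The count of 411 changed with any library left out, also a control library, though the controls do not enter this comparison. Such fits leave 1 library in a group and fewer libraries to measure the spread. A changed count therefore does not show that effects rested on 1 library. Without LPS + VD3 1 or LPS + VD3 2 the log2 fold change of Cd40 was -1.98 and -2.33, and that of Irf1 -1.29 and -1.17. The median of the interferon-stimulated genes was then -0.48 and -0.56, but -0.25 without LPS 1 and -0.70 without LPS 2. The source names hint at a pairing of equal numbers without stating it. The count was 169 with no filter beyond 1 count and 1152 with the replicate number as a block. Without LPS 1 it was 486, with 219 of the 241 higher and 138 of the 170 lower calls kept. The genes lower with VD3 had a median GC content of 54.5%, against 48.9% for those higher and 50.2% for all genes. The fold change followed GC across genes with Spearman's rho of -0.499, or -0.141 without LPS 1 and -0.603 without LPS 2. Passes gained without LPS 2, such as those of Cxcl10, Pparg and Top2a, rest on LPS 1 alone and cannot be told apart from that trend. In a fit with offsets per library that follow GC, chosen after seeing the data, 761 genes passed, with 235 of the 241 higher and 151 of the 170 lower calls kept. Of all genes named for this comparison, 38 passed upward, 18 of them with each of the 6 libraries left out in turn, and 37 passed downward, 2 of them so, Abca1 and Tgfbi. The 18 were Acpp, Ccl2, Ccl7, Cyp24a1, Gata6, Hbegf, Hey1, Hsph1, Irf4, Lif, Nppc, Osm, Pdgfb, Sall2, Srgap3, Ston2, Tgfbr2 and Vdr, which also passed under every other setting that tested them. Each of the other named genes lost its call without LPS + VD3 1, LPS + VD3 2 or either, and no sign turned. With no filter, calls lost included those of Tap1, Tap2, Ifit2, Ifit3, Irf7, Mx1, Nr1h3, Cxcl16, Cish, Nfkbie, Ier5, Dnajb9, F7, Naip2, Thbs4 and Lcn2. Batf3, Irf7 and Psmb9 (edgeR adjusted p = 0.116, 0.0539 and 0.0711) lost their calls without LPS 1.

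**Figure D4:**
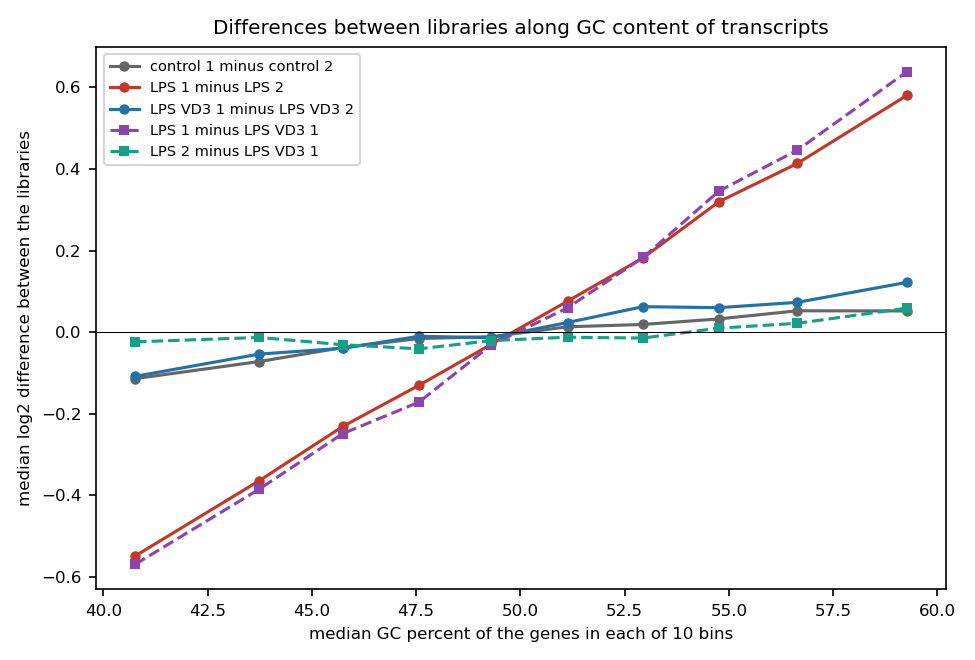
Median log2 difference between pairs of libraries in 10 bins of genes by GC percent of their transcripts. LPS 1 minus LPS 2 runs from -0.55 at 40.8% GC to 0.58 at 59.3%, while LPS 2 minus LPS + VD3 1 stays between -0.04 and 0.06.

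The response to LPS was next compared with the effect of VD3 gene by gene. Genes that answered LPS were chosen by the mean of both LPS groups against control. Where VD3 has no effect and the groups vary alike, this choice does not shift the VD3 comparison. A real effect of VD3 enters the choice, since the LPS + VD3 libraries are part of the mean. This favours genes that VD3 raised, such as Hbegf (6.7, 15.8 and 197 CPM in control, LPS and LPS + VD3), as raised by LPS. Of 1963 genes raised by LPS, 112 were higher with VD3, among them Il12b, Osm, Ccl2 and Hbegf, and 71 were lower, among them Cd40, Socs1, Abca1 and Irf1. If the VD3 calls fell evenly over the genes tested, 44.1 and 31.1 would be counted. Of 2105 genes lowered by LPS, 56 were higher with VD3, among them Vdr and Tgfbr2, and 57 were lower, among them Rhof and Abcg1, where 47.3 and 33.4 would be counted. Opposite to LPS were 42.9% of the VD3 calls among these genes. Neither set passed a test of lying to one side of the other genes with VD3 (limma camera adjusted p = 0.535 for each, adjusted over the 2 sets). The percentage was 58.4% without LPS 2, 20% without LPS + VD3 1 and 25% without LPS + VD3 2. The remaining 115 of the 411 genes did not answer LPS by this choice. With the choice by LPS against control alone, 64.3% of the VD3 calls were opposite to LPS. The first choice favours calls in the direction of LPS and the second calls against it, so both percentages depend on the choice.

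**Figure D5:**
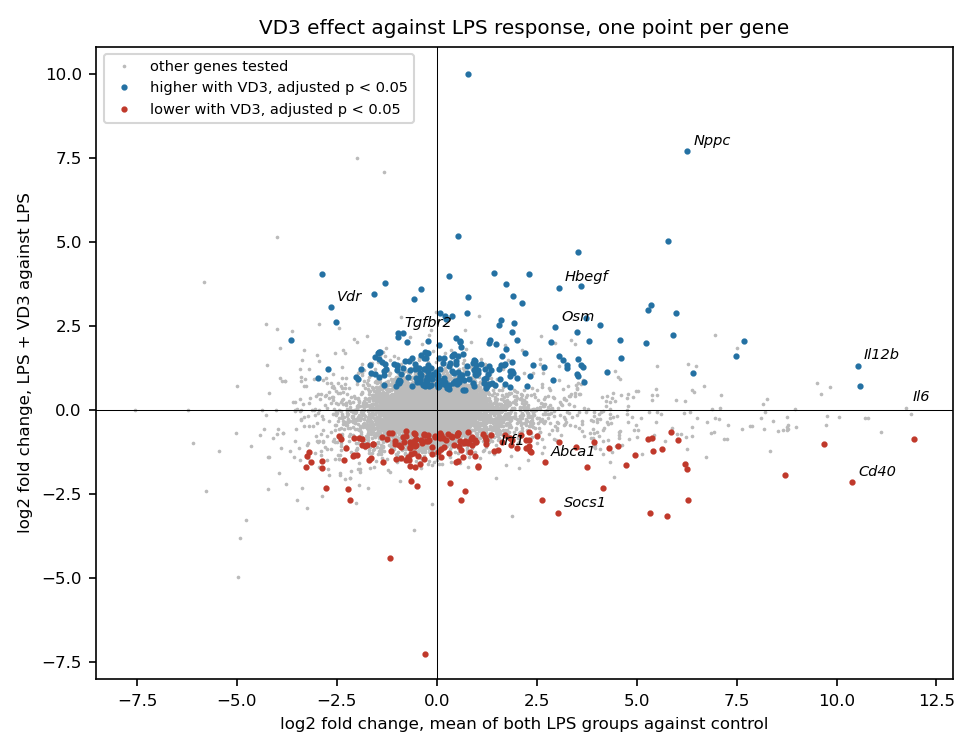
Log2 fold change with VD3 on top of LPS (vertical) against the mean log2 change of both LPS groups from control (horizontal), 1 point per gene tested, with genes that passed the edgeR test for VD3 in colour. Vdr and Tgfbr2 lie left of 0 and above it, Cd40, Socs1 and Abca1 right of 0 and below it. Points of genes with few counts depend on the prior count of the fit.

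LPS + VD3 against control gave the response to both treatments together. Il6 rose by 11.78 ± 0.40 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.17e-08), Tnf by 6.12 ± 0.22, Il1b by 7.37 ± 0.22 and Irg1 by 10.94 ± 0.24 on the log2 scale. Cxcl10 had 2 counts in control and 6666 with both treatments, Il12b 2 and 4334, and Ifit3, whose reads may be shared with Ifit3b, was at least 276-fold higher. Hbegf rose by 4.87 ± 0.21 and Cyp24a1 by 5.78 ± 0.37 (edgeR adjusted p = 4.14e-06), and Vdr fell by 1.12 ± 0.17 (edgeR adjusted p = 0.0007). Klf4 fell by 6.60 ± 0.31, Plekha6 by 5.36 ± 0.36, the cannabinoid receptor Cnr2 by 5.18 ± 0.26 and the BH3-only gene Bmf by 4.81 ± 0.37, and C5ar2 had 185 counts in control and 2 with both treatments. Tgfbr2 was at 0.17 ± 0.14 (edgeR adjusted p = 0.37) and Pparg at -0.40 ± 0.15 (edgeR adjusted p = 0.0719), while Siglec5 fell by 1.09 ± 0.15, Tlr4 by 0.78 ± 0.25 and Abcg1 by 2.67 ± 0.17, and Marco, Cd14 and Abca1 rose by 1.34 ± 0.15, 4.07 ± 0.25 and 1.92 ± 0.18. Pparg passed downward in a fit of the compared libraries only (0.0153), with the replicate number as a block (0.0419), with GC offsets (0.0127) and without LPS 1 (0.00964) or LPS 2 (0.0148), as well as with upper-quartile or no scaling and in the deposited log2 table. Tlr4 lost its call with no filter and without either control or LPS + VD3 library. Nos2 and Ifnb1 were at least 11.5-fold and 4.11-fold higher, from 0 counts in control, and Ifnb1 lost its call without either control or LPS + VD3 library.

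All 16 cytokines rose, as did 32 of 33 interferon-stimulated genes, 18 of 20 feedback regulators, 14 of 17 chemokines with 1 that fell, and 14 of 22 genes of Tlr4 signalling with 1 that fell. Of 25 cell cycle genes 19 fell, such as Mcm7 (-1.96 ± 0.18), of 22 cholesterol synthesis genes 17, such as Dhcr7 (-2.74 ± 0.23), and of 15 LXR and lipid export genes 8 with 1 that rose. Antigen presentation genes rose in 7 of 18 cases and fell in 2, antioxidant genes rose in 7 of 15 and fell in 1, inflammasome genes rose in 6 of 12 and fell in 3, and alveolar macrophage identity genes rose in 5 of 28 and fell in 14, with Kcnn3 at -2.74 ± 0.17. Adjusted over the list alone, 22 cell cycle and 19 cholesterol synthesis genes fell, and 8 antigen presentation genes rose. VDR targets rose in 6 of 14 cases and fell in 4. Alternative activation genes rose in 3 of 10 and fell in 3, immediate early genes rose in 7 of 15 and fell in 1, phagocytic receptors rose in 2 of 17 and fell in 6, glycolysis genes rose in 4 of 20 and fell in 6, and unfolded protein response genes rose in 3 of 15 and fell in 2. Of the ribosomal protein genes 1 rose and of the oxidative phosphorylation genes 1 fell. Among markers of other cells, 3 of 5 neutrophil and 3 of 5 monocyte markers rose, the latter with 1 that fell, as did 1 of 4 dendritic cell markers with 2 that fell, and 1 epithelium and 1 lymphocyte marker fell.

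By edgeR's quasi-likelihood test, 1895 genes were higher and 1854 lower than in control at adjusted p under 0.05, 35% of the genes tested, and 1045 and 1172 of them changed by at least 2-fold. The count of 3749 genes was 2126 without control 1, 2144 without control 2 and 2135 without LPS + VD3 2, and the share of higher calls, 50.5%, was 39.6% with upper-quartile scaling (median shift -0.13), 25.9% without scaling beyond library size (median shift -0.327) and 24.2% and 24.4% in the deposited log2 table. Limma's camera called 12 lists with adjusted p between 6.86e-22 (interferon-stimulated genes) and 0.0488: cytokine, interferon-stimulated, feedback, chemokine, Tlr4 signalling, antigen presentation, antioxidant and inflammasome genes upward, and cell cycle, cholesterol synthesis, LXR and alveolar macrophage identity genes downward. With an estimated correlation the lowest adjusted p over all lists was 0.125. Without LPS + VD3 1 the identity and antigen presentation calls were lost (limma camera adjusted p = 0.0967 and 0.0561), and the inflammasome call was lost without LPS 2 (0.0503), LPS + VD3 2 (0.0515) and with GC offsets (0.147). The antioxidant list's median of 0.32 was smaller than the shift of the unscaled fit.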

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

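The fits without scaling and with GC offsets were chosen only after the data were seen; the other alternatives were planned. In LPS against control the count of 3411 genes stayed within 1.5 times under every setting that kept the 6 libraries, and ranged from 1940 to 4829 with 1 library left out. In LPS + VD3 against control, with 3749 genes, the same held and the range was 2126 to 5410. In LPS + VD3 against LPS the 411 genes became 169 with no filter beyond 1 count, where 15510 genes shared the adjustment. They became 258 in a fit of the compared libraries only, 761 with GC offsets, and from 55 to 3670 with 1 library left out. The fit of the compared libraries only has fewer samples, but it gave 5236 genes in LPS + VD3 against control. In LPS against control it gave 2984. Fewer samples alone therefore do not account for the 258. The main fit also draws its spread from the control libraries, which lay closest together. Their chi-square per degree of freedom was 2.51, against 26.2 for the LPS and 9.9 for the LPS + VD3 libraries. Whether they raised the 411 was not tested. In LPS + VD3 against LPS, RLE and upper-quartile scaling, at least 1 CPM, DESeq2, limma-voom, the legacy fit, both fits of the deposited CPM and no scaling gave 352 to 543 genes. No gene called in any comparison was called with the opposite sign under these settings. A group with 1 library left was assumed to vary like the other groups. With a library of a treated group left out, the choice of LPS response genes can shift the VD3 comparison even where VD3 has no effect. The replicate number as a block gave 1152 genes with VD3; the source names of the LPS + VD3 libraries hint at such a pairing without stating it, and the deviations correlated at 0.172, 0.0894 and 0.196 over 2 numbers, so whether 411 or 1152 is nearer stays open. Il1b and Top2a gained calls with it. The share of VD3 calls opposite to LPS, 42.9%, was 33.9% with no filter, ranged from 20% to 58.4% with 1 library left out, and was 64.3% with LPS response genes chosen by LPS against control alone. That choice put the raised set downward (0.000184) and the lowered set upward (0.00317) by limma's camera before adjustment. Both directions were turned from the choice by the mean of both LPS groups, and both calls were lost with an estimated correlation (0.0617 and 0.0802). Of the lists, an estimated correlation called 0, 0 and 0 in LPS against control, LPS + VD3 against LPS and LPS + VD3 against control. The preset one called 10, 6 and 12. As the estimated one missed even the interferon list after LPS, where all 33 genes rose, its lack of calls with VD3 does not show a lack of shifts. With VD3 against LPS the estimate was 0.256 for interferon, 0.549 for antigen presentation and 0.417 for oxidative phosphorylation genes. It was 0.117 for feedback, 0.0563 for cell cycle and -0.0395 for LXR genes. Where it lies above the preset 0.01, the p-values with the preset one may be too small. Fry, which does not compare a list with other genes, called 19, 4 and 18. With VD3 against LPS the 4 were VDR targets and alternative activation upward, and LXR and stromal marker genes downward (fry adjusted p = 0.0476 each). They held only the LXR list of the 6 that camera called, and not the interferon (fry adjusted p = 0.0812), antigen presentation (0.328) or feedback (0.198) lists. Where no construction is named, the cause was not tested. Of the named genes' values under other settings, 1022 of 1079 in LPS + VD3 against LPS kept their call or lack of one, 52 lost and 5 gained it, and with 1 library left out 390 of 522 kept, 124 lost and 8 gained it. In LPS against control 889 of 897 and 430 of 438 kept it, and in LPS + VD3 against control 332 of 340 and 158 of 168. Signs turned in 11 values, none of which passed. On simulated counts the test recovered 6.2% of 1.5-fold changes in LPS against control. The share was 6.3% in LPS + VD3 against LPS and 12.7% in LPS + VD3 against control. Those simulations changed fewer genes than passed in the data, which makes the adjustment stricter, and depth was not varied. In LPS against control 2056 of the 3411 genes called changed by at least 2-fold and the rest by less.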

Other observations

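The tests of GC offsets, of libraries within a group, of interferon-stimulated genes without LPS 1 and of the shared LPS libraries were chosen only after the results they bear on had been seen. The bound for the GC trend without LPS 1 was set before that value was seen, and so was the planned choice of LPS response genes. Genes in the next paragraph were chosen after their values were seen, all from those that passed edgeR's quasi-likelihood test in LPS + VD3 against LPS.

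Genes outside the lists also moved with VD3 on top of LPS. Acpp, an acid phosphatase, rose by 2.98 ± 0.15 on the log2 scale (SE, n = 2; edgeR adjusted p = 1.87e-05), after a rise of 3.79 ± 0.17 with LPS alone. The growth factors Pdgfb and Pdgfa rose by 2.88 ± 0.18 and 2.80 ± 0.39 (edgeR adjusted p = 3.95e-05 and 0.00365), complement C3 by 1.10 ± 0.14 and the aryl hydrocarbon receptor Ahr by 1.35 ± 0.21. Nop58, Gar1 and Dkc1, proteins of small nucleolar ribonucleoproteins, and Polr1a, the large subunit of RNA polymerase I, rose by 1.24 ± 0.20, 1.21 ± 0.28, 0.89 ± 0.18 and 0.96 ± 0.18. With LPS alone Nop58 and Dkc1 had fallen by 1.12 ± 0.20 and 1.39 ± 0.17. Tgfbi, an extracellular matrix protein, fell by 1.49 ± 0.15 (edgeR adjusted p = 0.00064) after a fall by 1.57 ± 0.15 with LPS, and the adhesion molecule Icam1 fell by 0.89 ± 0.15 after a rise of 2.31 ± 0.15. The adenosine receptors Adora2a and Adora2b fell by 1.21 ± 0.21 and 1.23 ± 0.19, having risen by 6.02 ± 0.33 and 2.98 ± 0.21 with LPS, and Areg, an epidermal growth factor family ligand like Hbegf, fell by 1.33 ± 0.27. Acpp, Pdgfb and Tgfbi passed with each of the 6 libraries left out. Each of the others lost its call without LPS + VD3 2, Gar1 also without LPS 1 (edgeR adjusted p = 0.0932).

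Genes lower with VD3 were richer in GC than genes higher with VD3, with a rho of -0.499 between GC and the fold change. Libraries of 1 group with no treatment between them also differed along GC, the smallest rho in size being 0.189 and the largest 0.669 for the LPS libraries, so part of the trend may be technical. It did not come from LPS 1 alone, since without LPS 1 rho was -0.141, beyond the bound of -0.1 set in advance, yet most of it went with that library and the remainder is no larger than the rho within the control and LPS + VD3 groups. A GC trend as the whole cause of the lower calls is argued against by the 151 of 170 that were kept with GC offsets. A batch of LPS 1, whose title is of another number series, and a biological difference of that culture cannot be told apart, as both fall on 1 library.

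The list of 33 interferon-stimulated genes lay downward with VD3 at a median of -0.48, but only 6 of them fell. Without LPS + VD3 1 or 2 these calls were lost, while the median was -0.48 and -0.56. Camera of limma did not call the list with an estimated correlation (adjusted p = 0.628). Without LPS 1 the median was still -0.25 with 28 of 33 genes below 0, so the direction did not need LPS 1. The size of the shift went down by about as much as it kept, and without LPS 2 the median was -0.7. The LPS libraries thus differed from each other on this list. As the -0.25 rests on LPS 2 alone, a difference between libraries cannot be told apart from an effect of VD3. The median GC of these 33 genes, 48.7%, lay below the 50.2% of all genes, while the genes lower with VD3 were rich in GC. Such a trend would lift this list rather than lower it, which argues against GC content as the cause of its shift. The fit with GC offsets could therefore hardly remove the shift and adds no separate test (median -0.56, limma camera adjusted p = 6.76e-10). A dampening of the interferon response by VD3 may be a candidate explanation, as a hypothesis found and tested on the same libraries. The lost call says little, since an estimated correlation also gave no call for this list in LPS against control, where all 33 genes rose (limma camera adjusted p = 0.0886). The hypothesis stays open because fry did not call the list (adjusted p = 0.0812) and because Ifnb1 itself had 30 and 10 counts.

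Among genes raised by LPS against control alone, 62.5% lay below 0 with VD3, and of genes lowered 60.2% lay above 0, as if VD3 turned the LPS response back. Simulations with no VD3 effect gave 52.7% to 58.6% and 53.2% to 58.6% for this choice, because a high value in the LPS libraries enters both comparisons. Chosen by the mean of both LPS groups, 47.3% of raised genes lay below 0, inside the simulated 47.1% to 52.7%. Of lowered genes 46.1% lay above 0, under the simulated 46.8% to 52.6% and so to the side away from a turn. A real effect of VD3 enters this choice and moves the shares to that side, so they do not speak against a turn. The shared libraries may therefore account for part of the apparent turn. The 62.5% and 60.2% lie above the simulated ranges, but the simulations drew genes independently, with no GC trend and no real effects of VD3. LPS 1 and LPS 2 differed over many genes together (rho with GC of 0.669), so real ranges may be wider. Whether the shared libraries account for all of the turn cannot be told from these simulations. A reversal by VD3 of part of the response, as in Cd40 and Socs1, stays open and was not tested apart from these calls.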
